A study of Mus musculus with 8 samples.

How the data were processed

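Small RNA was sequenced from mouse bone marrow-derived macrophages, which are macrophages grown from marrow cells with the growth factor M-CSF (the equivalent of 20 ng/ml, 3 days of culture). The mice were a C57BL/6 and 129 mix with over 90% C57BL/6. They were wild type or carried a knockout of RBP-J, the DNA-binding protein through which Notch receptors act on transcription. Cells were unstimulated or treated with the inflammatory cytokine TNF for 24 hours. The labels give 8 libraries in 4 groups of 2, prepared per the labels' protocols with the Illumina TruSeq small RNA kit.

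Values came from 2 deposited tables with 1 column per group in each. In the first, the authors gave CPM (read counts scaled to a fixed total of miRNA reads per library) for 452 mature miRNAs with their arms, and every listed miRNA exceeded 5 CPM in at least 1 library, the lowest row maximum being 5.34. In the second, the deposited values carry no unit name and were read as RPKM (reads scaled to hairpin length and to a fixed total of reads per library) for 371 miRNA hairpin genes with Ensembl identifiers. That reading rests on the values: multiplied by the gene length in GENCODE M21, which held 363 of the 371 identifiers, 94.8% to 95.2% of low values were whole multiples of 1 read at a tolerance of 0.1 reads. The submitters' processing notes name CASAVA 1.8.2, the Illumina base calling and demultiplexing software. The aligner, counter and genome build were not given in the sources used here.

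Whole reads were recovered from the CPM table, in which 100% of the low values were whole multiples of 1 read at that tolerance. Its libraries held 321328 reads for unstimulated wild type, 562308 for wild type with TNF, 353138 for unstimulated knockout and 848630 for knockout with TNF. A value of 1 read was thus 3.11, 1.78, 2.83 and 1.18 CPM. Libraries of the RPKM table held about 21712260, 19340687, 14892634 and 13574375 reads in the same order, as inferred from the step of the values. The total they are scaled to covers more than the listed miRNAs, so a change in the share of miRNA reads moves every miRNA of a library together. No row of the RPKM table held a zero, against 129 rows of the CPM table. Its values may thus stop at 1 read, or it may leave out miRNAs absent from a library.

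The tables give different features in different units, so no contrast was taken across them. The mean over the 8 libraries, which sets the filter and the 10 most abundant, pools both, and RPKM values weigh most in it. Arms of a miRNA were summed in the CPM table and hairpin copies in the RPKM table, which gave 329 and 350 miRNA numbers, 197 of them in both. Near-identical family members and hairpin copies share reads, and the tables divide them differently. For example, miR-146b had 4861 to 21399 CPM but 6.08 to 15.4 RPKM, and let-7a had 20723 to 45260 CPM but 390 to 581 RPKM, so single members of such families are uncertain.

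The main test was limma 3.58.1 (lmFit, eBayes with a trend) in R 4.3.3 on log2(value + 1), over 184 miRNAs with a mean of at least 5 across the 8 libraries. It fitted 4 groups with the deposited table as a block, so that each contrast was taken within a table and the spread was the disagreement between the 2 tables. Tests were two-sided with Benjamini-Hochberg adjustment at 0.05 in each of 7 comparisons. These were TNF in each genotype, the knockout under each treatment, the interaction, and both effects averaged. A log2 fold change on the log2(value + 1) scale understates the change of low miRNAs. Each ± after a fitted log2 fold change is the moderated SE over the 2 tables. The CPM table is named as replicate 1 and the RPKM table as replicate 2, the numbers that the sample titles give, while column names carry none. The labels do not tie a number to an animal or a culture. Deviations from the group means correlated at 0.748 to 0.915 between groups of the CPM table, and the change of unit was not separated from other differences between the 2 sets of libraries. Labels do not say that replicates are separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

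For lists of miRNAs, camera was run with a preset correlation of 0.01 and, beside it, with an estimated correlation, for the 15 of 22 lists with at least 3 tested members. They covered TNF and NF-kB responsive miRNAs, Notch or RBP-J linked miRNAs, osteoclast promoting and restraining miRNAs, and myeloid miRNAs. Families and clusters were the clusters of miR-183 with miR-96 and miR-182, of miR-17/92 and its paralogs, of miR-23/27/24, of miR-221 with miR-222 and of miR-99b with let-7e and miR-125a, and the let-7, miR-29, miR-30, miR-15/16 and miR-181 families. Marker lists of other cells were erythroid, lymphoid, stromal, Dlk1-Dio3 cluster, epithelial, endothelial and platelet, and muscle and liver miRNAs. Lists overlap: miR-155, for example, stands in 4 of them, and miR-205 in both the lymphoid and the epithelial list. miR-182 and miR-183 also stand in the Notch or RBP-J linked and the osteoclast promoting lists, which are thus not independent of their cluster.

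The main test, camera, the lists, the first set of alternatives and the rule for naming miRNAs were written before the data were examined. The rule took up to 10 per direction among those that passed and moved the same way in both tables. Where fewer than 10 passed, it filled to 5 per direction by the largest smaller-of-2 within-table log2 fold change. It added up to 4 members per list by level, the 10 most abundant miRNAs, and miR-182, miR-183, miR-96, miR-155, miR-146a, miR-21a and miR-223. Other names were chosen after their values were seen. The plan also held fry, another list test, which is not reported here. Values adjusted over a list alone were not in the plan, nor were the shuffles of miRNAs. For the former, limma p-values were adjusted by Benjamini-Hochberg within the list, also where it had 2 tested members. Nothing was corrected over the 22 overlapping lists or the 7 comparisons.

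Alternatives of that first set were no block, pseudocounts of 0.25 and 10, no filter, a mean of at least 50, median-of-ratios scaling, each library left out in turn, and DESeq2 1.42.0 with the block on recovered reads. Added after seeing the data were edgeR 4.0.16 quasi-likelihood on recovered reads, both tables rescaled to the total of their listed miRNAs, and the more abundant arm alone. The count tests treat the reads inferred from the RPKM table as whole reads, which held for about 95% of its low values. The design had foreseen counts or CPM in both tables, and its test for normalized values was used.

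The limma fit was tested on simulated data with the real levels of the 184 miRNAs, 40 of them changed, in 20 simulations. For TNF averaged over genotypes, a log2 change of 2 was called in 81.5% of cases and one of 4 in 99.8%. For TNF in wild type the shares were 55.2% and 97.2%. Unchanged miRNAs were called in 1% of cases in both. The simulated noise was normal, independent between miRNAs and libraries, and of the spread that the fit estimated. No simulated library stood apart from the rest, as some real ones did, so these shares may not hold for the real data. Joins used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots used matplotlib 3.10.9. Hairpin positions are from GENCODE M21 on GRCm38, which may not be the build used upstream. Counting intervals (95%) cover counting error only, since reads without molecular identifiers are not independent molecules. Rbpj itself is a protein-coding gene outside these tables, so the knockout label could not be checked here.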

Results

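To examine which microRNAs TNF induces in macrophages and which depend on RBP-J, small RNA profiles of wild-type and RBP-J knockout bone marrow-derived macrophages were compared with and without 24 hours of TNF. Each of the 4 groups had 2 libraries, 1 in a CPM table and 1 in an RPKM table. Libraries of the CPM table held 321254 to 848446 reads of listed miRNAs, and those of the RPKM table about 6647014 to 12701599. In the RPKM table the listed miRNAs took 49.98% of reads in unstimulated wild type (95% Wilson interval 49.96 to 50) and 65.67% with TNF (65.65 to 65.69). The knockout values were 44.63% (44.61 to 44.66) and 53.17% (53.15 to 53.2).

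By mean value over the 8 libraries, in which RPKM values weigh most, miR-22, miR-21a, miR-27b and let-7f stood among the 10 most abundant miRNAs. In the CPM table miR-22 ranged from 69197 to 111734 CPM over the 4 groups, miR-27b from 96696 to 108973, let-7f from 72804 to 111144 and miR-21a from 48455 to 92850. In the RPKM table miR-22 ranged from 1164780 to 1915070 RPKM, miR-21a from 969516 to 1280350 and miR-27b from 424450 to 1049880. The myeloid miR-142a had 10504 to 14315 CPM and 86062 to 134003 RPKM. The rest of the 10 were miR-92a, miR-10a, miR-30d, miR-146a, miR-222 and miR-99b. Of these miR-99b had 476 to 3898 CPM, less than miR-16 (14422 to 49162 CPM) and miR-423 (34225 to 49576 CPM), which are outside the 10. The cluster of miR-183, miR-96 and miR-182 was far lower, at 252 to 1936 CPM for miR-182 and 28.0 to 239 CPM for miR-183, while miR-96 was listed in the RPKM table alone, at 0.434 to 1.39 RPKM or 1 to 2 reads. The cluster lies on chromosome 6 of GRCm38, minus strand, with Mir182 at 30165918 to 30165992, Mir96 at 30169446 to 30169551 and Mir183 at 30169668 to 30169737, and GENCODE M21 annotates no host gene around them.

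In wild-type macrophages, TNF went with higher miR-155, the miRNA most often tied to inflammatory activation, in both tables. It stood at 177 and 391 CPM without and with TNF and at 2655 and 8523 RPKM, a log2 fold change of 1.41 ± 0.54. Ranked by the smaller of the 2 within-table values of the same sign, the higher side was led by miR-129 (4.04 ± 1.21), miR-127 (2.00 ± 0.84, from 0 to 3 reads in the CPM table), miR-101b (1.33 ± 0.58) and miR-365 (1.32 ± 0.80). The lower side was led by miR-2137 (-3.02 ± 1.10), miR-467e (-2.16 ± 1.07), miR-122 (-1.87 ± 1.05), miR-138 (-1.86 ± 0.92) and miR-184 (-1.17 ± 0.88). Reads of these 5 in the CPM table without and with TNF were 4 and 0, 3 and 0, 11 and 2, 5 and 1, and 3 and 2, and miR-122 had 3 and 1 in the RPKM table. The cluster members miR-182 and miR-183 had 0.95 ± 0.66 and 1.01 ± 0.80, with within-table values of 1.59 and 1.74 in the CPM table and 0.31 and 0.28 in the RPKM table. The medians over all 184 miRNAs were -0.618 in the CPM table and 0.383 in the RPKM table. Both cluster members thus lay below the median of the RPKM table.

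None of the 184 miRNAs passed in limma for TNF in wild type (lowest adjusted p = 0.642), 12 had an unadjusted p under 0.05, and DESeq2 and edgeR on recovered reads called 0. In each comparison a share of 0.05 of the 184 is expected under that unadjusted p if no miRNA changed. Of the 11 TNF and NF-kB responsive miRNAs tested, 6 were higher and 2 lower in both tables, with a median log2 fold change of 0.54. These counts are against 0. Against the table medians over the 184 (-0.618 CPM, 0.383 RPKM), miR-21a (0.24) and miR-221 (0.30) were not higher in the RPKM table. By that measure miR-125a (-0.07 and 0.80) was higher in both tables. Within this list miR-222, a cell cycle regulator, had 0.98 ± 0.36 and miR-99b 1.14 ± 0.48, whereas miR-146a, a feedback inhibitor of NF-kB signalling, had -0.62 ± 0.34. Camera put this list, the let-7 family, the Notch or RBP-J linked list and the osteoclast promoting list above the other miRNAs (adjusted p = 0.0295 each). The calls were lost with adjusted p = 0.309 with an estimated correlation for all but let-7, and adjusted p = 0.844 with an estimated correlation for let-7. Adjusted over the list alone, miR-222 passed in its cluster with miR-221 (0.0424, 1 of 2), and none of the 184 did over all. When the unstimulated wild-type library of the RPKM table was left out, the median log2 fold change over the 184 went from -0.079 to -0.508. The baseline was then the unstimulated wild-type library of the CPM table alone, which stood apart from its table. The SD of its log2 ratios to the rest of that table was 1.386 times that among the rest. Without the wild-type TNF library of the RPKM table the median was -0.488.

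**Figure D1:**
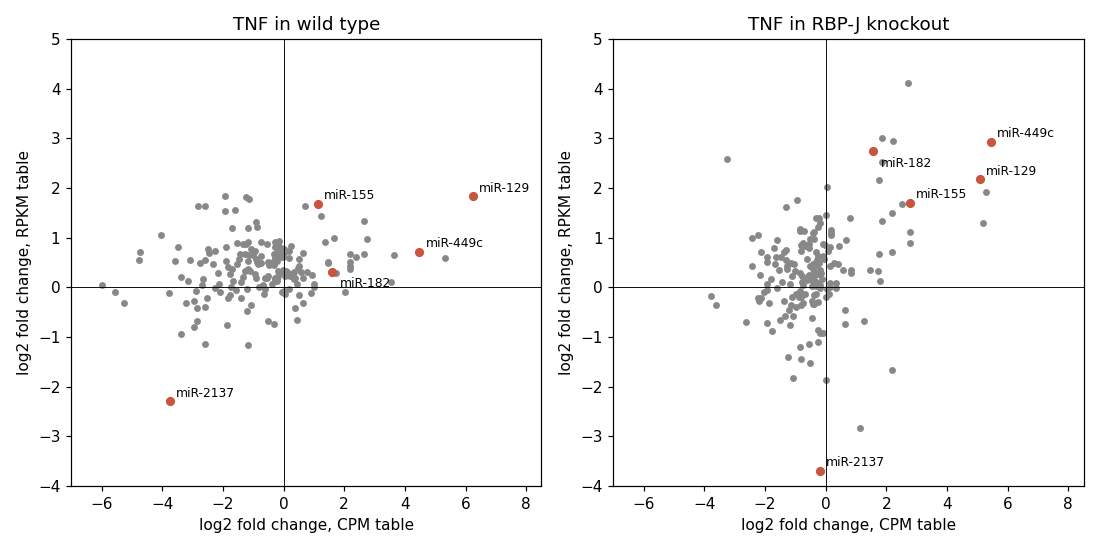
Log2 fold change with TNF in the CPM table (x axis) against that in the RPKM table (y axis) for 184 miRNAs, in wild type (left) and in RBP-J knockout (right); each point is 1 miRNA and 5 are marked. The correlation across miRNAs was 0.234 in wild type and 0.375 in the knockout.

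Agreement of the tables on the TNF effect was measured in each genotype. Pearson correlations across the 184 miRNAs, which are not independent replicates, were 0.234 for wild type and 0.375 for the knockout, without a test of the difference. Within 1 table the effects of TNF in the 2 genotypes, which share no library, correlated at 0.586 (CPM) and 0.62 (RPKM). Relative to the median of each table, 17 miRNAs moved at least 2-fold the same way in both tables with TNF in the knockout, 14 of them higher, against 6.5 after shuffling (10000 shuffles of miRNAs, permutation p = 0.0001, the smallest they can give). In wild type there were 10 against 5 (permutation p = 0.0141), and for TNF averaged 10 against 4.6 (0.0087). These shuffles treat miRNAs as independent.

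In RBP-J knockout macrophages, miR-155 again stood higher with TNF, at 156 and 1075 CPM and at 2814 and 9177 RPKM (log2 fold change 2.24 ± 0.54). The cluster members miR-182, a promoter of osteoclast differentiation, and miR-183 were higher in both tables as well. miR-182 went from 657 to 1936 CPM and from 334 to 2232 RPKM (2.15 ± 0.66), and miR-183 from 65.1 to 239 CPM and from 53.7 to 436 RPKM (2.43 ± 0.80). By the same ranking the higher side was led by miR-449c (4.18 ± 1.08), miR-129 (3.63 ± 1.21), miR-31 (3.59 ± 1.27), miR-449a (3.41 ± 1.04) and miR-365 (2.58 ± 0.80). Several of these were scarce: miR-449c, miR-129 and miR-31 had 0 reads in the unstimulated CPM libraries of both genotypes, and 36, 28 and 32 reads with TNF in the knockout. The lower side was led by miR-181d (-1.45 ± 0.78), miR-362 (-1.33 ± 0.83), miR-181c (-1.31 ± 0.78), miR-150 (-1.12 ± 1.13) and miR-146b (-1.04 ± 0.70). The neutrophil and myeloid miR-223 had -1.23 ± 0.53 and miR-21a 0.15 ± 0.30.

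None of the 184 passed in limma for TNF in the knockout (lowest adjusted p = 0.278), 16 had an unadjusted p under 0.05 (15 higher and 1 lower; 15 and 2 with median-of-ratios scaling, 12 and 4 after rescaling to the listed miRNAs), and edgeR called 0. DESeq2 on recovered reads called 5, all higher: miR-155 (log2 fold change 2.43, adjusted p = 0.0034), miR-365 (2.92, 0.0034), miR-183 (2.56, 0.00902), miR-449a (4.05, 0.00902) and miR-182 (2.23, 0.0434). Adjusted over the list alone in limma, miR-155 passed among the 11 TNF and NF-kB responsive miRNAs (0.0208), and miR-155, miR-182, miR-183 and miR-34c passed among the 14 Notch or RBP-J linked ones. miR-155 also passed among the osteoclast restraining (0.0189) and myeloid (0.0132) miRNAs, and miR-222 (0.0248) and miR-125a (0.04) in their clusters. miR-182 and miR-183 both passed in their own cluster (0.0127 each), but the study turned on this cluster, so its direction is not independent evidence. Nor is their passing in the Notch or RBP-J linked list, which contains them. Camera put the NF-kB list (adjusted p = 0.00796) and the Notch list (0.00751) above the others, with adjusted p = 0.3 with an estimated correlation for both. Leaving out 1 library changed the limma count to 6 without the unstimulated or the TNF wild-type library of the CPM table, 7 without the unstimulated or the TNF wild-type library of the RPKM table, and 4 without the knockout TNF library of the RPKM table.

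**Figure D2:**
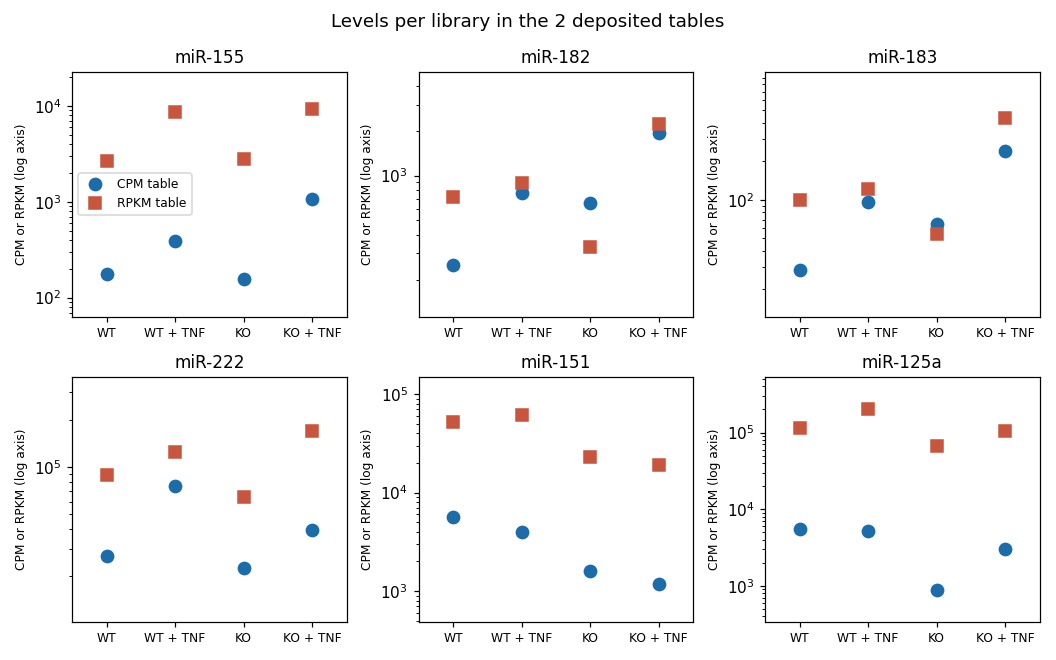
Level per library (log axis, CPM or RPKM) of 6 miRNAs in wild type (WT) and RBP-J knockout (KO) with and without TNF; circles are the CPM table and squares the RPKM table, 1 library per point. miR-155 was higher with TNF in all 4 within-table pairs, and miR-151 lower in the knockout in all 4.

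Averaged over genotypes, miR-155, miR-129, miR-449c, miR-365 and miR-183 were the leading 5 on the higher side with TNF by the same ranking. The log2 fold change was 1.83 ± 0.38 for miR-155 (adjusted p = 0.0802), 3.83 ± 0.86 for miR-129 (0.0802), 3.39 ± 0.77 for miR-449c (0.0802), 1.95 ± 0.57 for miR-365 (0.164), 1.72 ± 0.57 for miR-183 (0.21) and 1.55 ± 0.47 for miR-182 (0.181). The abundant miR-222 had 1.04 ± 0.25 and miR-21a 0.37 ± 0.21. miR-2137 had -2.48 ± 0.78, miR-874 -1.08 ± 0.61, miR-126a -0.74 ± 0.57 and miR-92b -0.70 ± 0.53, and miR-146b had -1.31 in the CPM table and -0.68 in the RPKM table. Mir155 lies on chromosome 16 at 84714140 to 84714204, in an exon of its host lincRNA Mir155hg, and Mir222 on chromosome X at 19146893 to 19146971.

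None of the 184 passed in limma for TNF averaged, 26 had an unadjusted p under 0.05 (20 higher and 6 lower; 20 and 12 with median-of-ratios scaling, 13 and 15 after rescaling to the listed miRNAs), edgeR called 0, and DESeq2 called 10. Those 10 were miR-101b, miR-129, miR-147, miR-155, miR-182, miR-183, miR-365, miR-449a and miR-449c higher and miR-2137 lower. The median log2 fold change over the 184 went from -0.129 to -0.342 without the unstimulated wild-type library of the RPKM table. The wild-type baseline was then the library of the CPM table that stood apart (1.386). The median was -0.314 and -0.264 without the wild-type and knockout TNF libraries of the RPKM table, and 0.051 without the wild-type TNF library of the CPM table. Adjusted over the list alone, 4 of the 11 TNF and NF-kB responsive miRNAs passed, all higher: miR-155 (0.00783), miR-222 (0.0122), miR-99b (0.0423) and miR-147 (0.0462), against 0 over all 184. So did miR-182, miR-183, miR-31 and miR-99b of 11 osteoclast promoting miRNAs (0.0346 each), 5 of 14 Notch or RBP-J linked ones, miR-155 and miR-34c of 10 osteoclast restraining ones, and miR-155 of 7 myeloid ones. Both tested members passed on that scale in the cluster of miR-221 and miR-222 and in that of miR-99b and miR-125a. Both tested members also passed in that of miR-182 and miR-183 (0.0126 each), not independent evidence since the study turned on it. The same holds for miR-182 and miR-183 in the osteoclast promoting and Notch lists, which contain them. Camera put the NF-kB and Notch lists above the others (adjusted p = 0.00541 each, and adjusted p = 0.276 with an estimated correlation). The osteoclast promoting list had a median log2 fold change of 0.22 (camera adjusted p = 0.0786), and the osteoclast restraining list had a median of -0.20, a mean of 0.14 and a camera adjusted p of 0.724, ranked upward.

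Other families and cell type markers did not pass for TNF averaged. Median log2 fold changes were 0.11 for the 8 let-7 miRNAs, 0.14 for the 3 miR-29, -0.64 for the 4 miR-15/16, -0.30 for the 4 miR-181 and -0.50 for the 7 myeloid miRNAs. They were 0.001 for 9 miRNAs of the miR-17/92 clusters, -0.04 for 5 of the miR-30 family and -0.01 for 5 of the miR-23/27/24 clusters, and the last 2 became positive with median-of-ratios scaling (0.09 and 0.11). For the miR-23/27/24 clusters the mean was -0.18 while camera ranked them upward. Among markers of other cells, 3 lymphoid miRNAs had a median of -1.19, 5 stromal ones -0.15 and 7 epithelial ones -0.40. The lymphoid 3 were miR-150, miR-342 and miR-205, which also stands in the epithelial list. miR-205 had 0 to 12 reads in the CPM libraries. Single tested markers were miR-486a of red cells (-0.13 ± 0.42), miR-127 of the Dlk1-Dio3 cluster (0.71 ± 0.59), miR-126a of endothelium and platelets (-0.74 ± 0.57) and miR-122 of liver (-1.40 ± 0.74). The lymphoid marker miR-342 had 7718 CPM in the unstimulated wild-type library of the CPM table against 960 to 2959 in the rest of that table. The median over all 184 was -0.13 for TNF averaged and -0.01 with median-of-ratios scaling. The same scaling moved it from -0.08 to 0.07 for TNF in wild type, from -0.10 to 0.01 for TNF in the knockout, from -0.23 to -0.10 for the unstimulated knockout, from -0.12 to -0.02 for the knockout with TNF and from -0.13 to -0.02 for the knockout averaged.

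Without stimulation, the knockout libraries had lower miR-125a and miR-151 than wild type in both tables. miR-125a had 5536 CPM in wild type and 886 CPM in the knockout, and 116098 and 66737 RPKM (log2 fold change -1.72 ± 0.44). miR-151 had 5658 and 1608 CPM, and 52052 and 23042 RPKM (-1.49 ± 0.39). By the same ranking the lower side was led by miR-184 (-3.75 ± 0.88), miR-879 (-2.44 ± 0.79), miR-205 (-2.42 ± 1.07), miR-34c (-2.24 ± 1.08) and miR-195a (-1.78 ± 0.88). Reads of these 5 in the CPM table in wild type and knockout were 3 and 0, 1 and 0, 12 and 1, 1 and 0, and 5 and 1. Higher values were miR-181c (1.02 ± 0.78), miR-30a (0.99 ± 0.48), miR-181d (0.90 ± 0.78), miR-181b (0.83 ± 0.38) and miR-34a (0.70 ± 0.57). miR-182 and miR-183 had 0.14 ± 0.66 and 0.16 ± 0.80 and stood on opposite sides in the 2 tables, while miR-155 had -0.05 ± 0.54 and miR-146a -0.75 ± 0.34.

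None of the 184 passed in limma for the unstimulated knockout (lowest adjusted p = 0.191), 5 had an unadjusted p under 0.05 (all lower; 5 higher and 6 lower with median-of-ratios scaling, 5 and 5 after rescaling to the listed miRNAs, 4 and 10 in edgeR), and DESeq2 and edgeR called 0. Adjusted over the list alone, miR-125a passed as lower among the NF-kB (0.0325), Notch (0.0413) and osteoclast restraining (0.0295) miRNAs and in its own cluster (0.0059). Camera put the let-7 family (median log2 fold change 0.49, adjusted p = 0.000483) and the miR-181 family (0.86, 0.00378) above the others, with adjusted p = 0.536 with an estimated correlation for both. The median log2 fold change over the 184 went from -0.234 to -0.651 without the unstimulated wild-type library of the RPKM table. Unstimulated wild type was then the library of the CPM table alone, which stood apart from its table (1.386). Of the 7 stromal miRNAs with a mean of at least 20 RPKM, 6 were lower in the knockout libraries of the RPKM table under both treatments, as were 49.7% of all miRNAs at that level. Of the 7 stromal miRNAs in the CPM table at any level, 1 was lower under both, against 31.7% of all miRNAs with a mean of at least 20 CPM, and their median log2 ratio of knockout to wild type was -0.186 without and 0.484 with TNF. The stromal sets of the tables share only miR-10a, miR-10b, miR-143 and miR-152. The fibroblast and smooth muscle miR-143 had 16593 RPKM in wild type and 3380 in the knockout, against 80.9 and 51.0 CPM.

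With TNF, the knockout libraries had higher miR-182 and miR-183 and lower miR-151 and miR-210 than wild type in both tables. miR-182 had 763 CPM in wild type and 1936 CPM in the knockout, and 887 and 2232 RPKM (log2 fold change 1.34 ± 0.66), and miR-183 had 1.58 ± 0.80. miR-210, the main hypoxia-responsive miRNA, had 509 and 121 CPM and 3153 and 911 RPKM (-1.92 ± 0.58). miR-151 had 3934 and 1189 CPM and 60939 and 19042 RPKM (-1.70 ± 0.39). Further values of the same sign were miR-2137 (1.58 ± 1.10), miR-30a (0.98 ± 0.48) and miR-500 (0.95 ± 0.91) on the higher side, and miR-466h (-1.98 ± 1.05), miR-195a (-1.63 ± 0.88) and miR-127 (-1.48 ± 0.84) on the lower. Of these miR-2137, miR-500, miR-466h, miR-195a and miR-127 had 0 to 3 reads in the CPM libraries compared. miR-155 had 0.78 ± 0.54, miR-223 -0.46 ± 0.53, miR-146a -0.50 ± 0.34 and miR-21a -0.20 ± 0.30.

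None of the 184 passed in limma for the knockout with TNF (lowest adjusted p = 0.244), 4 had an unadjusted p under 0.05 (all lower; 3 higher and 3 lower with median-of-ratios scaling, 3 and 2 after rescaling to the listed miRNAs and in DESeq2 and edgeR), and edgeR called 0. DESeq2 called miR-151 as lower (log2 fold change -1.60, adjusted p = 0.0139). No list passed with camera, and adjusted over the list alone miR-182 and miR-183 had 0.0775 each in their cluster, a list the study itself turned on. Relative to the table medians, 10 miRNAs moved at least 2-fold the same way in both tables, 7 of them lower, against 2.7 after shuffling (permutation p = 0.0001, the smallest 10000 shuffles can give). For the unstimulated knockout there were 7, all lower, against 5.6 (permutation p = 0.314). For the knockout averaged there were 8, all lower, against 2.5 (permutation p = 0.0012), and for the interaction 7 against 5.3 (0.259). These shuffles, too, mix scarce and well-counted miRNAs, so an excess does not establish agreement.

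Averaged over treatments, miR-151 fell in the knockout. It was lower in all 4 within-table pairs of libraries, with a log2 fold change of -1.60 ± 0.27 (limma adjusted p = 0.0299), and within-table means of -1.77 (CPM) and -1.43 (RPKM). Mir151 lies on chromosome 15, minus strand, at 73254815 to 73254882, in an intron of Ptk2, the focal adhesion kinase gene, on the same strand. Below the threshold, miR-184 had -2.44 ± 0.63, miR-195a -1.71 ± 0.62, miR-879 -1.66 ± 0.56, miR-34b -1.55 ± 0.62 and miR-125a -1.29 ± 0.31. On the higher side were miR-30a (0.98 ± 0.34), miR-183 (0.87 ± 0.57), miR-182 (0.74 ± 0.47), miR-500 (0.65 ± 0.64), miR-181b (0.62 ± 0.27) and miR-98 (0.53 ± 0.29). In the CPM libraries miR-184, miR-879, miR-34b and miR-500 had 0 to 3 reads and miR-195a 0 to 5.

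miR-151 was the 1 call among 184 in limma; edgeR called it too, and DESeq2 called it and miR-30a (log2 fold change 1.11, adjusted p = 0.0169). The miR-151 call ended with a pseudocount of 10 (adjusted p = 0.0648), without the block (1.0), and without the unstimulated wild-type library of the CPM table (0.0948), the unstimulated knockout library of the CPM table (0.334) or the RPKM table (0.0947), or the knockout TNF library of the CPM table (0.0696). Its log2 fold change was -1.595 with a pseudocount of 10, -1.598 without the block, and -1.416 to -1.781 over all settings tried. Without the block, the change of unit between the tables counts as spread, so that setting could hardly give a call. Over the 184, the median log2 fold change went from -0.125 to -0.338 without the unstimulated wild-type library of the RPKM table. It was -0.345 without the wild-type TNF library of the CPM table. The median was 0.013 and -0.248 without the wild-type and the knockout TNF libraries of the RPKM table. Adjusted over the list alone, miR-125a passed as lower in 4 lists, the osteoclast restraining one (0.02) among them, and miR-99b with it in the cluster they share (0.0149). Camera put let-7 (median log2 fold change 0.26, adjusted p = 0.0101) and miR-181 (0.29, 0.0404) above the others, with adjusted p = 0.66 with an estimated correlation for both. Other medians were -0.40 for the NF-kB list, -0.60 for the Notch list, 0.04 for miR-17/92, -0.27 for miR-23/27/24, -0.41 for miR-29, -0.44 for miR-15/16, -0.26 for osteoclast restraining, -0.91 for lymphoid and -0.58 for epithelial miRNAs. The lymphoid and epithelial lists share miR-205. Camera ranked upward 3 lists with a negative median, namely the miR-30 family (-0.001, mean 0.14, and 0.12 with median-of-ratios scaling), the osteoclast promoting list (-0.17) and the stromal list (-0.43), while the myeloid list had a median of 0.02 and a mean of -0.11.

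Ranked likewise, the difference between the TNF effects of the 2 genotypes was led by miR-449a (3.03 ± 1.48), miR-184 (2.61 ± 1.25), miR-449c (1.58 ± 1.53), miR-1960 (1.57 ± 1.39) and miR-879 (1.55 ± 1.12) on the higher side in the knockout. On the lower side were miR-127 (-2.59 ± 1.18), miR-181c (-1.71 ± 1.10), miR-181d (-1.43 ± 1.10), miR-210 (-1.18 ± 0.82) and let-7a (-0.89 ± 0.61). Several were scarce in the CPM libraries: miR-184, miR-879 and miR-127 had 0 to 3 reads and miR-1960 0 to 5. There miR-449a had 36 reads in the knockout with TNF and 2 to 4 in the rest. miR-449c had 12 and 36 reads with TNF in wild type and knockout, and 0 without. miR-182 and miR-183 had 1.20 ± 0.93 and 1.42 ± 1.13, which came from the RPKM table (2.43 and 2.71) and not from the CPM table (-0.04 and 0.12). miR-155 had 0.83 ± 0.76. None of the 184 passed in limma for the interaction (lowest adjusted p = 0.988), 0 had an unadjusted p under 0.05, and DESeq2 and edgeR called 0, with 2 and 3 at an unadjusted p under 0.05. When the unstimulated wild-type library of the RPKM table was left out, limma called 2, miR-24 and miR-7a, and when its wild-type TNF library was left out, 1, miR-24. Camera put the let-7 family (median -0.37, adjusted p = 0.0146) and the miR-181 family (-0.92, 0.0396) below the others, with adjusted p = 0.886 with an estimated correlation for both. miR-24 had 37199 CPM in the unstimulated wild-type library of the CPM table against 1385 to 3460 CPM in the rest of that table, and 5237 to 12915 RPKM in the RPKM table.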

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

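All tests of explanations in this part were chosen after the result was seen. Those for the table difference and the stromal miRNAs were redefined after a first run, whose values are given beside the later ones. The camera tests were set beforehand.

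3 miRNAs outside the comparisons, each listed in 1 table, were at least 4-fold higher with TNF in both genotypes and had at least 100 reads in their highest library. miR-378a, from the CPM table, was 7.05-fold higher in wild type (95% counting interval 6.68 to 7.44) and 5.97-fold in the knockout (5.75 to 6.21), reaching 47486 CPM. miR-6539, from the same table, was 14.0-fold (7.23 to 31) and 22.2-fold higher (12.0 to 46.5), from 9 and 10 reads. miR-455, from the RPKM table, was 6.02-fold (4.96 to 7.36) and 9.1-fold higher (5.94 to 14.5), and its hairpin lies in an intron of the collagen gene Col27a1 on chromosome 4. With 1 library per group these folds have no replicate check.

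By the camera test with a preset correlation, the interaction of TNF and knockout ranked lower for 2 families than for the other miRNAs. The median interaction on the log2 scale was -0.368 for let-7 (adjusted p = 0.0146) and -0.922 for miR-181 (0.0396), with adjusted p = 0.886 with an estimated correlation for both. Of the 8 let-7 miRNAs 7, and of the 4 miR-181 miRNAs 2, lay below 0 in both tables. The medians were -0.59 in the CPM table and -0.227 in the RPKM table for let-7, and -1.192 and -0.634 for miR-181. The 2 lower miR-181 members were the scarce miR-181c (-1.71 ± 1.10, 12 to 40 reads in the CPM libraries) and miR-181d (-1.43 ± 1.10, 11 to 25 reads). The more abundant miR-181a and miR-181b had -0.17 ± 0.48 and -0.42 ± 0.53, and 0.004 and 0.099 in the RPKM table. The unstimulated wild-type library of the CPM table (1.386) and the knockout TNF library of the RPKM table (1.362), which both enter this contrast, stood apart from the rest of their tables, as described next.

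The TNF effect in wild type differed between the tables. Counting error at the low depth of the CPM table would weaken scarce miRNAs most, but the correlation between the tables was -0.051 over the 108 miRNAs with a mean of 50 or more in each table and 0.234 over all 184; the first version of this test found the variance between the tables to be 57.9 times that of counting. With a linear trend on hairpin GC taken out, the correlation was 0.005 (-0.121 in the first version, over the 94 miRNAs at 50 or more in all libraries). This cannot decide on GC, since the correlation would rise only if a shared TNF effect lay beneath the trend. The unstimulated wild-type library of the CPM table stood apart, with log2 ratios to the rest of its table whose SD was 1.386 times that among the rest (1.433 in the first version), against 0.843 in the RPKM table, and it may account for part of the difference. The knockout TNF library of the RPKM table stood apart by 1.362 as well, and no biological explanation was tested.

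Stromal miRNAs were lower in the knockout libraries of the RPKM table. Scaling was first tested on the 5 stromal miRNAs of the joined tables, where their median of -0.306 after median-of-ratios scaling lay between the bounds and left it undecided; the test was then moved to the RPKM table alone, where the median of -1.23 argues against it. Of the 7 stromal miRNAs with a mean of 20 or more RPKM, 85.7% were lower under both treatments, against 49.7% of all such miRNAs (87.5% of 8 in the first version, by the maximum), so fewer stromal cells in these cultures may explain the pattern, although this test comes close to restating it. Against that, the most abundant, miR-10a, was higher. Of 7 stromal miRNAs in the CPM table only miR-100 was lower under both treatments, although 31.7% of all miRNAs with a mean of 20 or more CPM were. The sets of the tables differ in part: miR-10a, miR-10b, miR-143 and miR-152 stand in both. miR-145a, miR-196a and miR-214 stand in the RPKM set alone, and miR-100, miR-199a and miR-199b in the CPM set alone. miR-199a and miR-199b have equal values in 3 of the 4 libraries of the CPM table, and so few members decide little. An effect of the knockout within macrophages stays open and untested.

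miR-182 and miR-183 were higher with TNF in the knockout. Scaling is argued against, since their mean log2 fold change was 2.398 after median-of-ratios scaling, with a mean SE of 0.683. Epithelial cells, which also express this cluster, cannot be told apart: the median TNF effect of the 5 tested miR-200 family members was 0.155, with values from -1.09 to 1.03 and SEs from 0.965 to 1.384. The tables were opposed for miR-200a, miR-200b and miR-429. With TNF in the knockout these went from 6, 124.7 and 34.8 to 40.9, 384.1 and 75.4 RPKM, but from 8.5, 150.1 and 25.5 to 0, 60.1 and 18.9 CPM. The tables went the same way for the rest of the family. miR-141 rose from 43.8 to 55.3 RPKM and from 2.8 to 11.8 CPM. miR-200c fell from 240.4 to 193.2 RPKM and from 11.3 to 2.4 CPM. The knockout TNF library of the RPKM table, where miR-182 and miR-183 had log2 fold changes of 2.74 and 3.00 against 1.56 and 1.86 in the CPM table, stood apart from the rest of its table (1.362). An effect of TNF stays open, and its difference from that in wild type did not pass in the interaction test.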

How the results depend on the processing

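The alternatives added after seeing the data were edgeR on recovered reads, rescaling to the listed miRNAs and the more abundant arm alone. Each gave as many calls as limma in all 7 comparisons. So did a pseudocount of 0.25, no filter, a mean of at least 50 and median-of-ratios scaling. With no replicate block the count was 0 in all 7. That fit counts the change of unit between the tables as spread, so it could hardly give a call. With a pseudocount of 10 the knockout averaged went from 1 to 0. DESeq2 called 5 for TNF in the knockout, 1 for the knockout with TNF, 10 for TNF averaged and 2 for the knockout averaged; the cause was not tested. With each library left out in turn, the lone library of a group was assumed to vary like the others. This held even for a lone library that stood apart from its table (1.386 or 1.362). Counts then ranged from 0 to 16 for TNF in wild type, 0 to 7 for TNF in the knockout, 0 to 5 for the unstimulated knockout, 0 to 2 for the interaction, 0 to 23 for TNF averaged and 0 to 4 for the knockout averaged, and were 0 throughout for the knockout with TNF. Camera called 4 lists for TNF in wild type, 0 for the knockout with TNF and 2 in each of the other comparisons, and 0 in all with an estimated correlation. Without the replicate block it called 0 lists for TNF in either genotype and the interaction, 4 for the unstimulated knockout, and 1 each for TNF averaged and the knockout averaged. Depth limits the CPM table most, where 1 read was 1.18 to 3.11 CPM.

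Named miRNAs that reversed were all below the threshold, and the cause was not tested. For the unstimulated knockout, miR-183 was -0.002 with DESeq2, and miR-155 was 0.088 with median-of-ratios scaling, 0.109 with DESeq2, 0.107 with edgeR and 0.039 after rescaling to the listed miRNAs. With 1 library left out, log2 fold changes ranged from -0.758 to 0.411 for miR-223 with TNF in wild type and from -0.154 to 0.46 for miR-21a with TNF in the knockout. For the unstimulated knockout they ranged from -0.705 to 0.983 for miR-182, -0.577 to 0.9 for miR-183, -0.23 to 0.127 for miR-155, -0.185 to 0.661 for miR-21a and -0.128 to 1.331 for miR-223. With TNF, the knockout effect ranged from -0.507 to 0.107 for miR-21a and -1.044 to 0.126 for miR-223. The interaction of miR-146a ranged from -0.167 to 0.663. For the knockout averaged, miR-21a ranged from -0.193 to 0.23 and miR-223 from -0.294 to 0.436.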

Other observations

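The counts over splits of the libraries were settled after the result was seen: the fit was changed after a first run, and both versions are given. The single-table values were picked after the data were seen and carry no test.

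The miRNAs listed in 1 table alone held several large contrasts that the joined comparisons could not use. In the CPM table let-7e, of the miR-99b cluster, went from 2894 to 15489 CPM with TNF in wild type and from 3268 to 7064 CPM in the knockout, folds of 5.35 and 2.16. miR-191 was among the most abundant, at 67430 to 120496 CPM. miR-690 and miR-3473a had 1332 and 613 CPM in unstimulated wild type, and 25.9 to 76.5 and 10.7 to 42.5 CPM in the rest of that table.

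In the RPKM table miR-145a had 352 and 1118 RPKM in wild type without and with TNF, and 110 and 232 RPKM in the knockout. The fold of knockout over wild type was 0.45 without and 0.23 with TNF for miR-214, and 0.433 and 0.182 for miR-615, whose hairpin lies in an intron of Hoxc5. For miR-653 it was 0.0767 (95% counting interval 0.0536 to 0.107) and 0.11 (0.0712 to 0.162).

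Of the 35 splits of the 8 libraries into 4 and 4, 32 could be fitted with the table, the other factor and its interaction, as in the comparisons. For TNF averaged the real split called 0 miRNAs, so all 32 called as many by construction and the count decides nothing. The highest of the others called 13. At an unadjusted limma p under 0.05 the real split had 26 miRNAs, 5 of 32 had as many, and the highest other had 48. For the knockout averaged the real split called 1, 4 of 32 called as many, and the highest of the others called 29, so chance is not excluded. Among the 16 splits that take 2 libraries from each table, as the real one does, 3 called as many and the highest other called 5; 16 are too few for a share under 0.05. The split with 29 set the unstimulated wild-type library of the CPM table and the RPKM libraries other than unstimulated knockout against the rest, which takes unequal numbers from the tables; it points to a structure of the samples other than the groups, which was not tested. The first run left out the interaction, which leaves more residual degrees of freedom, and fitted 33 splits. There the real split called 4 for TNF (miR-129, miR-155, miR-222 and miR-449c), 3 of 33 called as many and the highest other called 7; for the knockout it called 1, miR-151, again with 3 of 33 and 7. That fit did not exclude chance for either comparison.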
